A study of Homo sapiens with 16 samples.

How the data were processed

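Peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood) were cultured for 18 hours, and total RNA was extracted with a phenol-based reagent and hybridised, as biotin-labelled cRNA, to an Affymetrix expression array, per the labels' protocols. The design holds 16 samples, 8 treated with 1,2,4-benzenetriol, a trihydroxylated metabolite of benzene, and 8 left untreated in medium. The labels print the dose as 15 µM run together with the compound's name. The first digit of that dose may belong to the name instead, which would make the dose lower. A short name in the treated samples' labels that ends in a digit is not explained, so the dose is uncertain. They do not state when within the 18 hours the compound was added.

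The deposited values are log2 signals, 1 per probe set and array, made by the authors with RMA (robust multi-array average), per the submitters' processing notes, whose version and settings are not given in the sources used here. The table has 22215 probe sets and 0 Affymetrix control probe sets. Array medians lay between 5.41 and 5.55, and no scanner files were used here, so background and spot quality could not be looked at. RMA fits all arrays together and compresses differences of dim probe sets, which makes small fold changes of weakly expressed genes smaller. The number of arrays limits the precision.

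Probe sets were named through a table of the platform's annotation. 19064 probe sets had 1 gene symbol, 1043 had several and 2108 had none, and a gene was never named from a probe set with several. These make up 11936 genes, each represented by its probe set with the highest mean over the 16 arrays. Probe sets of near-identical genes can bind each other's RNA, which concerns AKR1C1 and AKR1C2, CXCL1 with CXCL2 and CXCL3, the metallothionein genes and the HLA-DRB genes. 37 probe sets of sex-linked genes and of genes that tell donors apart stayed in the fit and are named in no table. No genome was used here and no coordinates are given.

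The treatment protocol puts the same cells in a pair of plates and the compound in 1 of them, and each sample code occurs once per group, so the codes were taken as pairs 1 to 8 and entered the model as a block. After removal of group means, partners correlated above 0.1 in 6 of 8 pairs, with a median of 0.31 against -0.06 for samples with different codes, and in 4 pairs each sample correlated best with its partner. A check on sex-linked genes found 0 of 8 pairs whose samples disagreed, and 1 sample with an intermediate value. It cannot detect an exchange of samples between donors of the same sex. The codes begin with C in 3 pairs (pairs 1 to 3) and H in 5 (pairs 4 to 8), and the meaning of the letters is not given in the sources used here. The labels call the 8 samples of each group biological replicates without saying whether they are separate donors.

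Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with pair and treatment, then eBayes, 7 residual degrees of freedom, two-sided) with Benjamini-Hochberg adjustment over all 22215 probe sets. A call means an adjusted p below 0.05. Fold changes are treated minus untreated on the log2 scale, with the standard error (SE) of limma's moderated fit. 22 functional gene lists and 10 lists of blood cell markers, 606 entries of which 539 were measured, were tested with camera at a preset correlation of 0.01, adjusted within each family. Camera with an estimated correlation and fry were chosen as alternatives beforehand. An exact two-sided sign-flip test of each list's mean change over the 8 pairs was added after the other splits of the samples had been seen, and its smallest possible p is 0.00781. Treatment by code letter was tested as an interaction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

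The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 12 genes with the largest rise and the 12 with the largest fall among called genes that moved the same way in all 8 pairs, up to 4 members with the smallest p of each list, and a fixed set of HMOX1, NQO1, GCLM, TXNRD1, CDKN1A, CYP1B1, CXCL8, IL1B, TNF, MPO and MT2A. SRXN1 and HSPA1A belong to that set too and have no probe set of their own. Genes named outside the rule are said to be so.

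The procedure was tested on simulated data with 200 of 22215 probe sets changed over 8 pairs. 39% of those changed 1.5-fold and 80% of those changed 2-fold were recovered, with 5 false calls. A list shifted by 0.40 passed camera with a preset and with an estimated correlation, and 0 other lists passed. The simulated noise was independent between probe sets, so this cannot show how camera behaves where the genes of a list move together. In the measured data the estimated correlation ran from -0.03 (LXR and PPAR lipid genes) to 0.95 (metallothioneins). The alternatives tried were no pair block, the pair as a random block, centring each array on its median, quantile normalization, leaving out the probe sets below the median signal, eBayes with trend and robust settings, array weights, leaving out each pair, each code letter alone, an exact sign-flip test, a stricter threshold or fold, 1 probe set per gene, the mean of a gene's probe sets. Added after seeing the data were the first principal component as a covariate, the 4 pairs with no array above 30 on it, the 6 pairs with no array below -30 on it, and the lists without PPBP and AKR1C2.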

Results

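Expression was measured with 22215 probe sets in 16 samples of cultured human PBMC, 8 exposed to 1,2,4-benzenetriol and 8 untreated partners from the same cells. The label prints 15 µM, and the dose was lower if the first digit belongs to the compound's name. 1,2,4-benzenetriol is a polyphenol formed from benzene in the body that oxidises readily, and the series asks how human cells respond to benzene metabolites. Array medians ranged from 5.41 to 5.55 on the log2 scale. The first principal component held 23.6% of the variance and spread mainly the untreated samples. The untreated samples of pairs 1, 3 and 8 and the treated sample of pair 5 scored above 30 on it (35.2 to 44.5), and the untreated samples of pairs 4 (-48.9) and 6 (-34.6) below -30. On the second component, with 14.4%, the treated sample scored above its partner in 8 of 8 pairs.

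The lists of inflammatory chemokines, NRF2 targets and platelet markers rose with benzenetriol, and those of MHC class II genes and B cell markers fell, in camera with a preset correlation. None of these 5 lists passed with an estimated correlation (adjusted p from 0.139 to 0.285). In fry the NRF2 and MHC class II lists (adjusted p = 0.0336 for each), platelet markers (0.0216) and B cell markers (0.0204) passed. The chemokine list did not (0.0867). CXCL5, a chemokine that attracts neutrophils, rose 6.82-fold, from a mean log2 signal of 8.86 to 11.63 (change 2.77, SE 0.38, n = 8 pairs, limma adjusted p = 0.00959). CCL7, a monocyte-attracting chemokine, rose by 2.37 (SE 0.19, adjusted p = 0.000351), and HES1, a transcriptional repressor downstream of Notch, by 2.45 (SE 0.34, adjusted p = 0.00940). ITGA2B, the alpha IIb integrin subunit of platelets, rose by 2.37 (SE 0.25, adjusted p = 0.00236). SPP1, which encodes osteopontin, fell the most among genes lower in all 8 pairs, with a change of -1.98 (SE 0.40, adjusted p = 0.0367), and IGHD, the heavy chain of immunoglobulin D on naive B cells, had the smallest adjusted p of the named genes (0.000307) with a change of -1.61 (SE 0.12).

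Among called genes higher in all 8 pairs, the others of the 12 largest rises were CXCL3 (2.44), MFAP3L (1.99), CLU (1.90), the myeloid activating receptor TREM1 (1.84), the protein kinase A subunit PRKAR2B (1.81), TMEM158 (1.78), the sterol hydroxylase CYP27A1 (1.66) and ARHGAP6 (1.66), all log2 changes with adjusted p between 0.00142 and 0.0255. The other large falls among called genes lower in all 8 pairs were those of TLR7 (-1.59), an endosomal receptor for single-stranded RNA, SERPINF1 (-1.45), the B cell-supporting cytokine TNFSF13 (-1.43), MS4A6A (-1.42), the tryptophan-degrading enzyme IDO1 (-1.34), HLA-DQB1 (-1.33), LY86 (-1.24), HLA-DPA1 (-1.19), the protease inhibitor CST3 (-1.16) and HLA-DRB1 (-1.07), with adjusted p between 0.00909 and 0.0289. A dimmer probe set of ITGA2B (-0.06), of MFAP3L (-0.08) and of ARHGAP6 (-0.14) moved the other way without passing the test, with mean log2 signals of 2.71, 3.19 and 3.52. Of 56 named genes that passed the test, 16 also passed in each of the 8 fits that left out 1 pair, among them CXCL5, CCL7, HES1, ITGA2B, CLU, IGHD and HLA-DRB1. The other 40 all lost the call without pair 6, where CXCL3, for example, had an adjusted p of 0.0544 and SPP1 lost it also without pair 2, 3, 4 or 7. Without the pair block 29 of the 56 no longer passed, CCL7 (adjusted p = 0.0634), CXCL3, CXCL8 and HLA-DRA among them. In the 6 pairs with no array below -30 on the first component, a fit chosen after seeing the data, CCL7, IGHD and ITGA2B were the 3 of the 56 that passed. Of the 91 named genes that did not pass, APOC1, APOE, DNAJB9, GCLM, HMGCS1 and ZMAT3 passed without pair 1. Without pair 5 the same held for APEX1, CSF3R, DUSP2, FPR1, GPNMB, LAMP3, MNDA, MS4A1 and PRF1, and without pair 8 for IL1B and SLC7A11. CSF3R had the smallest adjusted p of these (0.00823).

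**Figure D1:**
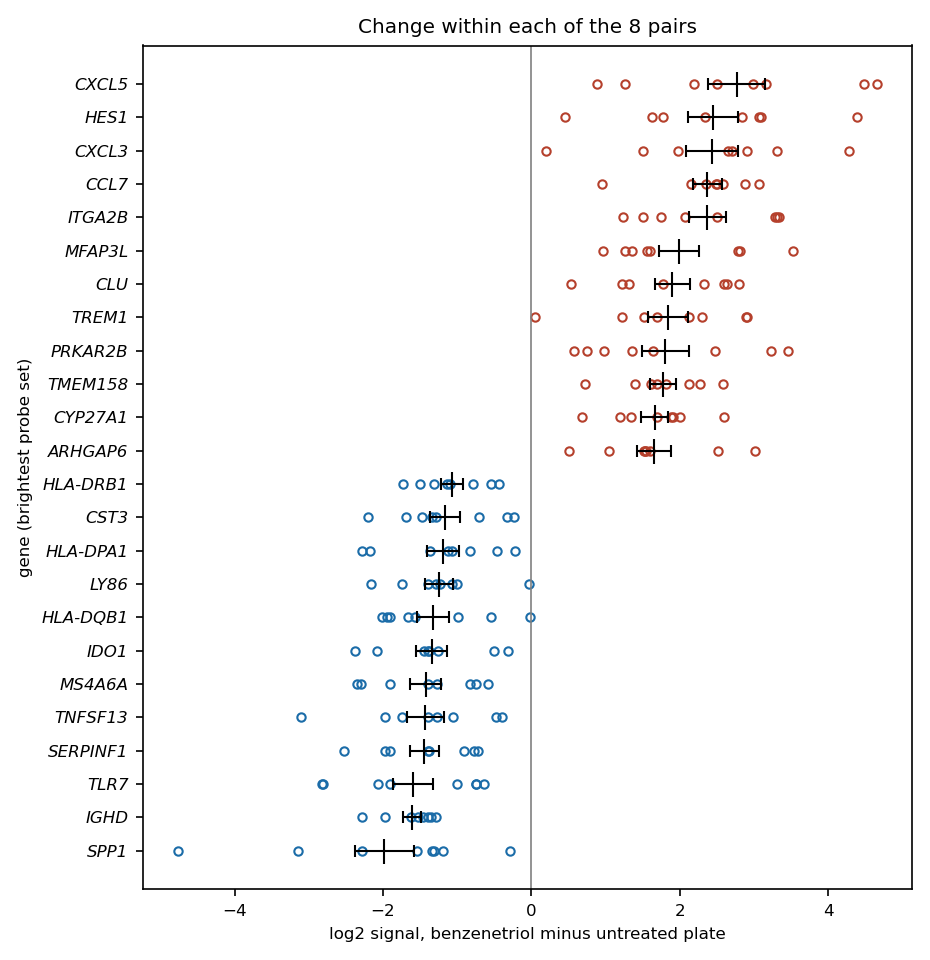
Log2 signal of the treated minus the untreated plate (horizontal axis) for the 12 largest rises and 12 largest falls among called genes that moved the same way in all 8 pairs. Open circles are the 8 pairs, the black bar is the mean with its SE from limma, and the pair changes of CXCL5 lie around a mean of 2.77 and those of SPP1 around -1.98.

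In all, 312 of 22215 probe sets passed the test, 206 higher and 106 lower with benzenetriol, and 249 of them differed at least 1.5-fold and 114 at least 2-fold. By gene, 186 of 11936 passed, 121 higher and 65 lower. The change had the same sign in all 8 pairs for 255 of the 312 probe sets. Without the pair block limma called 173 probe sets. An exact sign-flip test over the pairs called 0 (3156 at an unadjusted p below 0.05, against 3590 in limma). Its smallest possible p with 8 pairs is 0.00781, which 813 probe sets had (adjusted p = 0.213) while 3472 at that p would have been needed for any to pass. Its 0 therefore says little about single calls in limma. The count was 503 without pair 1, 176 without pair 2, 145 without pair 3, 70 without pair 4, 472 without pair 5, 45 without pair 6 and 57 without pair 7. It was 10 in the 6 pairs with no array below -30 on the first component, which leaves out pairs 4 and 6, and 307 in the 4 pairs with no array above 30.

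Inflammatory cytokines and chemokines rose as a list, with a mean change of 0.68 ± 0.52 (SD over 8 pairs). Of 31 measured members 8 rose, 0 fell and 23 did not pass, and 11 rose and 1 fell when adjusted over the list alone. Besides CXCL5, CXCL3 (2.44, SE 0.35) and CCL7, the neutrophil chemoattractant CXCL8 rose from 11.16 to 12.44 (change 1.28, SE 0.24, adjusted p = 0.0298) and TNF by 0.87 (SE 0.14, adjusted p = 0.0171). IL1B had a change of 1.14 (SE 0.27) in the same direction in 7 of 8 pairs and did not pass (adjusted p = 0.0720). The list's camera adjusted p was 1.54e-07 with the preset correlation, and adjusted p = 0.285 with an estimated correlation. CXCL8 lost its call without pair 2, 3, 4, 6 or 7, and TNF without pair 4, 6 or 7, with highest adjusted p of 0.0912 and 0.0613. The NF-kappaB target genes did not pass (adjusted p = 0.396, and 0.0297 in pairs 2, 4, 6 and 7 alone). TNFAIP2 rose by 0.65 (adjusted p = 0.0370, above the threshold without any 1 of pairs 2 to 8), 16 of 17 members did not pass, and NFKB1 (-0.48), RELB (0.36) and TNIP1 (0.37) went both ways. When adjusted over the list alone, 1 of its members rose and 1 fell.

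Targets of NRF2, the transcription factor of the oxidative and electrophile response, rose as a list by 0.48 ± 0.33 (SD over 8 pairs). Of 26 measured members 5 rose, 0 fell and 21 did not pass, and 15 rose when adjusted over the list alone. ABCC1, an exporter of glutathione conjugates, rose by 0.89 (SE 0.11, adjusted p = 0.00565), thioredoxin reductase TXNRD1 by 0.90 (SE 0.14, adjusted p = 0.0154), the quinone reductase NQO1 by 0.81 (SE 0.15, adjusted p = 0.0300) and the aldo-keto reductase AKR1C1 by 1.64 (SE 0.28, adjusted p = 0.0236). GCLM, a subunit of the glutathione-synthesising ligase, had a change of 0.67 in 8 of 8 pairs and did not pass (adjusted p = 0.0589), but passed after centring, after quantile normalization and with the pair as a random block (adjusted p = 0.0437, 0.0334 and 0.0254). Heme oxygenase HMOX1 was higher in 4 pairs and lower in 4 (0.17, SE 0.29, adjusted p = 0.822). Camera gave the list an adjusted p of 8.81e-12, and adjusted p = 0.218 with an estimated correlation. AKR1C1 and NQO1 lost their calls without pair 4, 6 or 7, NQO1 also without pair 3, and TXNRD1 without pair 4 or 6, with highest adjusted p of 0.0804, 0.0960 and 0.0666.

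Aryl hydrocarbon receptor targets rose by 0.32 ± 0.16 (SD over 8 pairs). CYP1B1, a cytochrome of estrogen and polycyclic hydrocarbon metabolism, doubled its signal, with a change of 1.01 (SE 0.14, adjusted p = 0.0113) from 10.91 to 11.93. TIPARP, a feedback inhibitor of the receptor, rose by 0.47 (SE 0.10, adjusted p = 0.0437) and lost the call without any 1 of pairs 2 to 8 (highest adjusted p 0.125). 3 of 6 members rose, NQO1 being the other, and 3 did not pass, CYP1A2 at -0.38 among them. When adjusted over the list alone 3 rose and 1 fell. The camera adjusted p was 0.0178, and adjusted p = 0.218 with an estimated correlation. That correlation was 0.0024, below the preset 0.01, so members moving together do not account for the higher p. The list passed fry (adjusted p = 0.0217). With the preset correlation its camera adjusted p was 0.0701 without pair 1, 0.190 in the H pairs alone and 0.271 in pairs 2, 4, 6 and 7 alone.

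Of 13 measured genes of benzene and phenol metabolism, 1 rose (NQO1), 1 fell and 11 did not pass, and the counts were the same when adjusted over the list alone. The gene that fell was ALDH2, the mitochondrial aldehyde dehydrogenase, with a change of -1.54 (SE 0.23, adjusted p = 0.0142), lower in 7 of 8 pairs and above the threshold without pair 6 (adjusted p = 0.0620) or pair 7. EPHX1 (0.42), SULT1A1 (-0.29) and MPO, the peroxidase that oxidises phenols (0.07, SE 0.12), did not pass. The list had a median of 0.0017 and a mean of -0.12 (-0.06 without pair 2), and its camera test, pointing down, did not pass (adjusted p = 0.680). Of 18 antioxidant enzymes 0 passed, over all probe sets or adjusted over the list alone, with GSS at 0.34, TXN at 0.47, PRDX1 at 0.37 and CAT at -0.39 (list adjusted p = 0.298, 7 members at an unadjusted p below 0.05 in limma). That list passed without pair 8 (adjusted p = 0.0468). The 7 metallothioneins, metal-binding proteins with near-identical sequences, had a list mean of -0.44 ± 0.88 with 0 members past the test, over all probe sets or adjusted over the list alone, and 1 at an unadjusted p below 0.05 in limma. MT1M stood at -0.90 (lower in 8 of 8 pairs, adjusted p = 0.196), MT1G at -0.59, MT1H at -0.48, MT1E at -0.38 and MT2A at -0.25. Without pair 8 these 5 changes were -0.52, -0.27, -0.19, -0.11 and -0.02, and the list mean was -0.13. The list passed camera downward (adjusted p = 0.0235), had adjusted p = 0.640 with an estimated correlation, and did not pass without pair 8 (0.211), without the pair block (0.254), with the pair as a random block (0.241) or in pairs 2, 4, 6 and 7 alone (0.337).

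**Figure D2:**
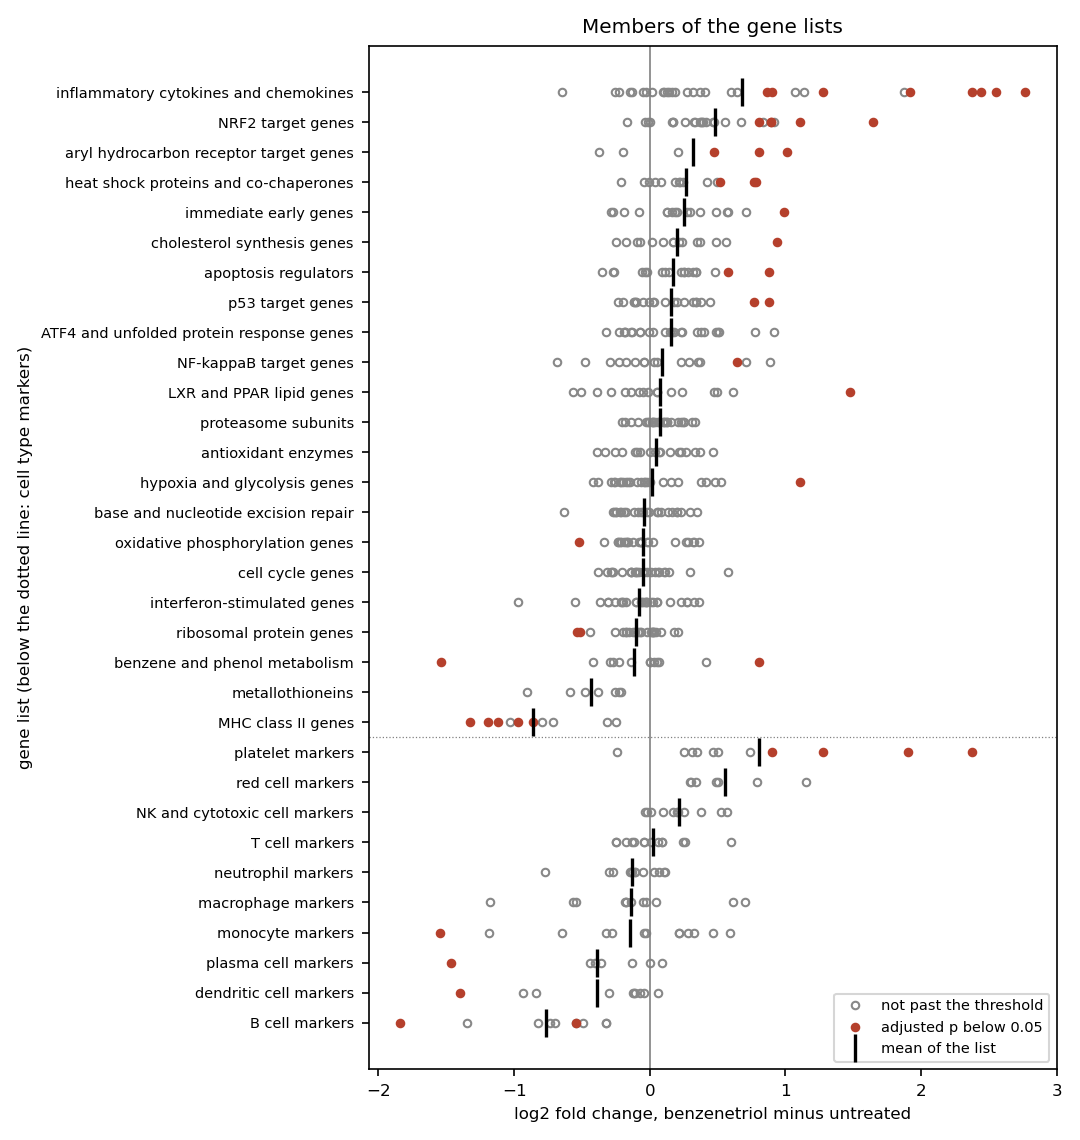
Log2 fold change, benzenetriol minus untreated (horizontal axis), of each measured member of the 22 functional lists and, below the dotted line, the 10 cell marker lists. Circles are genes, filled where the adjusted p was below 0.05, and black bars are list means, which run from -0.86 for MHC class II genes to 0.80 for platelet markers.

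Heat shock proteins and co-chaperones rose by 0.27 ± 0.24 (SD over 8 pairs), with 3 of 14 members higher, 0 lower and 11 not past the test, and 4 higher when adjusted over the list alone. The co-chaperones DNAJB4 (0.78, SE 0.13, adjusted p = 0.0203), BAG3 (0.77, SE 0.15, adjusted p = 0.0369) and DNAJB1 (0.52, SE 0.11, adjusted p = 0.0462) rose, and HSPH1 stood at 0.49 (adjusted p = 0.0707). Camera gave an adjusted p of 0.000173, and adjusted p = 0.285 with an estimated correlation. Targets of p53 had a mean change of 0.16 ± 0.18, with 2 of 21 members higher and 19 not past the test, and 3 higher when adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.368 with an estimated correlation). It did not pass without pairs 4 and 6 (0.108). The pro-apoptotic BH3-only gene PMAIP1 rose by 0.88 (SE 0.16, adjusted p = 0.0271) and the cell cycle inhibitor CDKN1A by 0.77 (SE 0.16, adjusted p = 0.0462), while ZMAT3 (0.45) and GADD45A (0.32) did not pass. Apoptosis regulators rose by 0.17 ± 0.21, and the 2 of 19 that passed, also when adjusted over the list alone, have opposite roles, PMAIP1 and the survival gene BCL2L1 (0.58, SE 0.09, adjusted p = 0.0162). CASP9 (0.25) and CASP8 (0.48) were among the 17 that did not pass, and the list had a camera adjusted p of 0.00208, and adjusted p = 0.368 with an estimated correlation. Each of these 6 called genes lost its call without pair 6 and without pair 7, and a dimmer probe set of BCL2L1 (-0.18) and of CASP8 (-0.55) moved the other way.

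Immediate early genes rose by 0.25 ± 0.29 (SD over 8 pairs), with FOSB (0.99, SE 0.16, adjusted p = 0.0185) as the member of 17 that passed, 16 not passing, and 2 higher when adjusted over the list alone. DUSP2 (0.57), IER2 (0.30) and NR4A3 (-0.28) did not pass, and the camera adjusted p was 0.00517, and adjusted p = 0.285 with an estimated correlation. In the C pairs alone the list's median was -0.0018 (adjusted p = 0.837). Of 25 ATF4 and unfolded protein response genes 0 passed limma over all probe sets (9 at an unadjusted p below 0.05) and 3 were higher when adjusted over the list alone, led by PPP1R15A (0.78, adjusted p = 0.0575), PDIA4 (0.50), DNAJB9 (0.51) and the cystine transporter SLC7A11 (0.92). That list had a mean of 0.16 ± 0.19 and passed camera upward (adjusted p = 0.0209), with adjusted p = 0.419 with an estimated correlation, 0.131 without pair 5, 0.0706 without pairs 4 and 6 and 0.0576 with the first component as a covariate. Cholesterol synthesis genes rose by 0.20 ± 0.22. SQLE, the squalene epoxidase, rose by 0.94 (SE 0.18, adjusted p = 0.0330), 14 of 15 members did not pass, SREBF2 (0.49), HMGCS1 (0.56) and EBP (0.37) among them, and 3 were higher when adjusted over the list alone. That list had a camera adjusted p of 0.00833, and adjusted p = 0.368 with an estimated correlation. FOSB and SQLE lost their calls without pair 6 (adjusted p = 0.0739 and 0.108) or pair 7, and SQLE also without pair 3 or 4.

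MHC class II genes, which present peptides to helper T cells, fell as a list by 0.86 on the log2 scale (SD 0.56 over 8 pairs, lower in 7 of 8 pairs). Of 10 members 5 fell, 0 rose and 5 did not pass, and 8 fell when adjusted over the list alone. HLA-DPB1 went from 10.57 to 9.70 (-0.86, SE 0.14, adjusted p = 0.0200), HLA-DQB1 changed by -1.33 (SE 0.22, adjusted p = 0.0206), HLA-DPA1 by -1.19 (SE 0.22) and HLA-DRA by -1.12 (SE 0.23, adjusted p = 0.0437). The camera adjusted p was 5.53e-10, and adjusted p = 0.218 with an estimated correlation. These 4 genes lost their calls without pair 6 and without pair 7, and HLA-DRA without any 1 of the pairs except pair 5. Markers of cells that carry class II moved with the list, as the B cell list changed by -0.77 and the dendritic cell list by -0.39, while the monocyte list had a mean of -0.15 ± 0.58 and did not pass. In pair 5 the monocyte mean was 1.05, and without that pair it was -0.32 (adjusted p = 0.0926) and the class II mean lay below it, with a difference of -0.68.

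B cell markers fell in 8 of 8 pairs, with a mean of -0.77 ± 0.52. TCL1A, expressed in naive B cells, changed by -1.84 (SE 0.35, adjusted p = 0.0312) and complement receptor CR2 by -0.54 (SE 0.11, adjusted p = 0.0425). The other 8 of 10 did not pass, with MS4A1 (CD20) at -1.35 (adjusted p = 0.0672) and CD79A at -0.49, and 9 fell when adjusted over the list alone. The camera adjusted p was 3.21e-08, and adjusted p = 0.139 with an estimated correlation. Plasma cell markers fell in 8 of 8 pairs (-0.39 ± 0.30), where IGHM, the immunoglobulin M heavy chain that B cells also carry, changed by -1.46 (SE 0.30, adjusted p = 0.0412), MZB1 (-0.40), IRF4 (-0.44) and TNFRSF17 (-0.36) were among the 6 of 7 that did not pass, and 4 fell when adjusted over the list alone. Its camera adjusted p was 0.00568, and adjusted p = 0.139 with an estimated correlation, and 0.0742 in pairs 2, 4, 6 and 7 alone. Dendritic cell markers also fell in 8 of 8 pairs (-0.39 ± 0.32), with FCER1A, the alpha chain of the IgE receptor, at -1.40 (SE 0.27, adjusted p = 0.0313) and 9 of 10 not past the test, LAMP3 (-0.93), CLEC10A (-0.84) and FLT3 (-0.30) among them, and 3 lower when adjusted over the list alone. Its camera adjusted p was 0.00568, and adjusted p = 0.198 with an estimated correlation, 0.0851 without pair 4 and 0.194 without pairs 4 and 6. TCL1A, CR2, IGHM and FCER1A each lost the call without pair 2, 4, 6 or 7.

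Monocyte markers did not pass (adjusted p = 0.774), and they went both ways, with the lectin FCN1 lower (-1.54, SE 0.29, adjusted p = 0.0314, above the threshold without pair 2, 4, 6, 7 or 8), MNDA at -1.19, FPR1 at -0.65 and CYBB at 0.59. 12 of 13 did not pass, and 3 fell when adjusted over the list alone. Their median change was -0.03, and 0.01 after quantile normalization. In the 4 pairs with no array above 30 on the first component (pairs 2, 4, 6 and 7), a fit added after seeing the data, the monocyte and macrophage lists passed downward (adjusted p = 0.0191 for each), and in the 6 with none below -30 neither passed (0.708 for each). Of 12 macrophage markers 0 passed limma over all probe sets (2 at an unadjusted p below 0.05) and 2 fell when adjusted over the list alone (camera adjusted p = 0.237), with GPNMB at -1.18, APOC1 at -0.56, MRC1 at 0.70 and FABP4 at 0.61. Of 13 neutrophil markers 0 passed limma over all probe sets or adjusted over the list alone (1 at an unadjusted p below 0.05, camera adjusted p = 0.268), with CSF3R at -0.77, LCN2 at -0.30, CXCR1 at -0.14 and FCGR3B at -0.27.

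Platelet markers rose in 8 of 8 pairs by 0.80 ± 0.51. Besides ITGA2B, CLU, a secreted chaperone that platelet granules also hold, rose by 1.90 (SE 0.24, adjusted p = 0.00615), the matrix protein SPARC by 1.27 (SE 0.19, adjusted p = 0.0124) and the platelet chemokine PPBP, already at 11.10 untreated, by 0.90 (SE 0.18, adjusted p = 0.0330). These 4 of 11 rose, 7 did not pass, and 5 rose when adjusted over the list alone. The list passed camera (adjusted p = 3.21e-08), with adjusted p = 0.139 with an estimated correlation. PPBP, which also counts among the cytokines, lost its call without pair 2, 4, 6, 7 or 8 and SPARC without pair 6 (adjusted p = 0.0596). Red cell markers rose by 0.55 ± 0.52, with 0 of 7 past limma's test over all probe sets (4 at an unadjusted p below 0.05) and 4 higher when adjusted over the list alone. Hemoglobin delta HBD stood at 1.15 (adjusted p = 0.0688), AHSP at 0.79, ALAS2 at 0.49 and HBB at 0.30, and the camera adjusted p was 3.31e-05, and adjusted p = 0.139 with an estimated correlation. The red cell list did not pass without the pair block (adjusted p = 0.0932) or with the pair as a random block (0.0742).

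NK and cytotoxic cell markers rose by 0.22 ± 0.26, higher in 7 of 8 pairs, with 0 of 11 past limma's test over all probe sets (2 at an unadjusted p below 0.05) and 2 higher when adjusted over the list alone. Perforin PRF1 stood at 0.53 (adjusted p = 0.0660), NKG7 at 0.57, GNLY at 0.38 and granzyme GZMB at 0.20. In camera the adjusted p was 0.00568, and adjusted p = 0.198 with an estimated correlation, 0.0580 without pair 4, where the mean was 0.13, and 0.0821 without pairs 4 and 6. It was 0.111 without the pair block and 0.0957 with the pair as a random block. T cell markers did not pass (mean 0.03, median -0.02, adjusted p = 0.566), with CD28 at 0.60, CD27 at 0.26, CD6 at 0.24 and CD2 at -0.25, 14 of 14 not past the test, and 1 higher when adjusted over the list alone. Their mean was -0.05 without pair 4 and 0.07 without pair 6. By the exact sign-flip test of list means, chosen after the other splits had been seen, all 6 marker lists that passed camera passed (adjusted p of 0.0195 for the B cell, platelet, plasma and dendritic cell lists, 0.0312 for red cells and 0.0391 for NK cells). By the same test 0 of the 22 functional lists did (7 at an unadjusted p below 0.05), and the smallest adjusted p was 0.0573 for 6 lists that include NRF2 targets, chemokines and MHC class II. These 3 had the same unadjusted p as the red cell list (0.0156), which was adjusted over 10 lists and not over 22, so these counts do not show that functional and marker lists differ. When labels were swapped within pairs, 11 of 100 such splits shifted as many functional lists in camera and 18 as many marker lists, the real split included. Splits that swap few pairs keep most pairs in the real direction, so they can hold part of a treatment effect. Nearly all other splits shifted some functional lists in camera, so passing it at the preset correlation is weak evidence by itself.

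**Figure D3:**
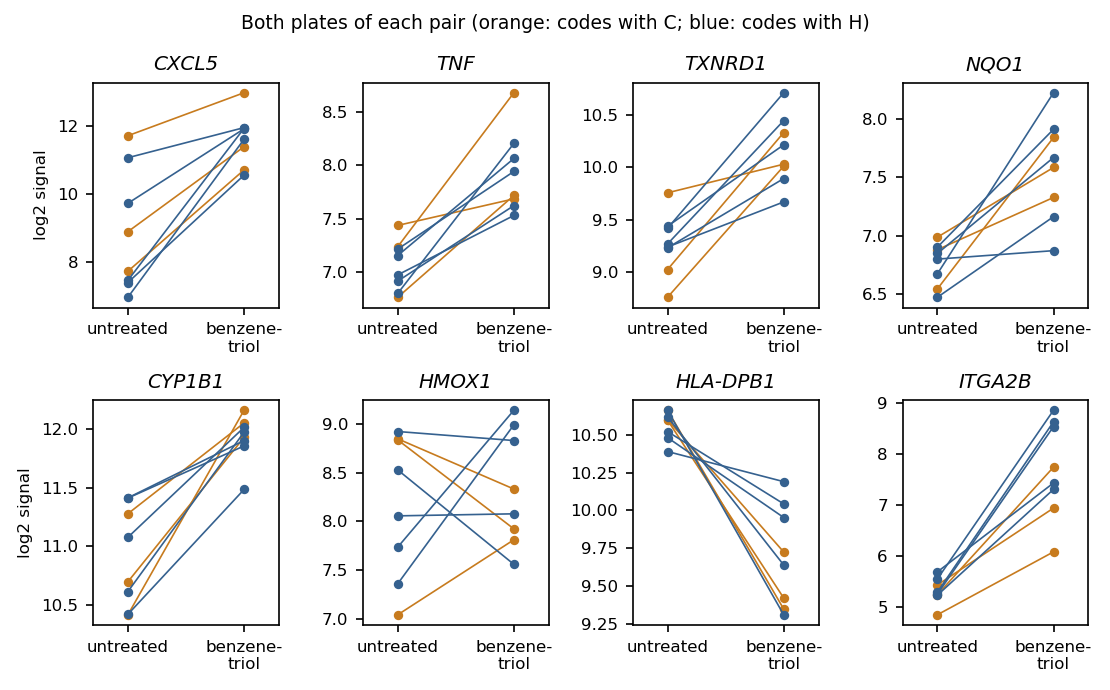
Log2 signal (vertical axis) of the untreated and the benzenetriol plate of each pair for CXCL5, TNF, TXNRD1, NQO1, CYP1B1, HMOX1, HLA-DPB1 and ITGA2B. Each line joins the plates of 1 pair, orange for codes starting with C and blue for H, and ITGA2B goes from a mean of 5.32 to 7.69 while the lines of HMOX1 go both ways.

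Several processes had lists that did not pass. Ribosomal protein genes had a mean of -0.10 (adjusted p = 0.0975). The list passed in 4 of 25 alternatives, without pair 4 (0.0458) or pair 7 (0.0234), without dim probe sets (0.0396) and with the mean of each gene's probe sets (0.0244). Its lower members were RPL10A (-0.54, adjusted p = 0.0437) and RPL6 (-0.52, adjusted p = 0.0462). RPL3 (-0.44) and RPS6 (-0.18) were among the 21 of 23 that did not pass, and 3 were lower when adjusted over the list alone. Oxidative phosphorylation genes (mean -0.05, adjusted p = 0.516) held 1 call, NDUFB8 (-0.52, adjusted p = 0.0300), also when adjusted over the list alone, while 23 did not pass, ATP5F1A at -0.34, NDUFB3 at 0.28 and NDUFA1 at 0.36 among them. The mean of that list was -0.001 without pair 2, -0.002 without pair 8 and -0.10 without pair 4. RPL10A, RPL6 and NDUFB8 lost the call without any 1 of pairs 2, 3, 4, 6, 7 and 8, and both dimmer probe sets of NDUFB8 (0.10 and 0.15) went the other way. Among hypoxia and glycolysis genes the vasodilator peptide ADM rose by 1.11 (SE 0.19, adjusted p = 0.0226, above the threshold without pair 6 or 7), 24 of 25 did not pass, PGK1 (-0.38), PFKFB3 (0.48) and SLC2A3 (0.41) among them, and 1 rose when adjusted over the list alone. A dimmer probe set of PGK1 moved the other way (0.59) and did not pass either. The hypoxia and glycolysis list's mean was 0.02, its median -0.06 and its camera test pointed down (adjusted p = 0.763). The mean was -0.03 without pair 4, -0.02 without pair 5 and 0.06 without pair 8. Among LXR and PPAR lipid genes the lipid droplet protein PLIN2 rose by 1.47 (SE 0.20, adjusted p = 0.00909; -0.14 in a dimmer probe set), 16 of 17 did not pass, APOC1 (-0.56), APOE (-0.39) and CPT1A (0.49) among them, and 2 rose and 2 fell when adjusted over the list alone. Its median was -0.01, which turned positive (0.03) after quantile normalization, its mean 0.08, and its camera test pointed up (adjusted p = 0.680).

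Excision repair (-0.04), interferon-stimulated (-0.08), cell cycle (-0.05) and proteasome genes (0.08, list means) held 0 calls of 25, 28, 25 and 25 members, over all probe sets or adjusted over the list alone, in limma, with 7, 4, 4 and 2 at an unadjusted p below 0.05. Their camera adjusted p were 0.680, 0.873, 0.396 and 0.101. Single pairs moved these means. Excision repair stood at -0.08 without pair 4, interferon-stimulated genes at 0.01 and cell cycle genes at -0.01 without pair 1. The proteasome mean was 0.01 without pair 4 and 0.13 without pair 8. The proteasome list passed in 7 of 25 alternatives, which were leaving out pair 2 (adjusted p = 0.0166), pair 3 (0.0462) or pair 8 (0.00746), the H pairs alone (0.00450), quantile normalization (0.0253), the mean of each gene's probe sets (0.0247) and the 4 pairs with no array above 30 on the first component (0.0466). The repair endonuclease APEX1 stood at -0.63 (adjusted p = 0.0991), POLE at 0.35, LIG1 at 0.30 and ERCC4 at -0.27. IFITM1 (0.27) and IFI6 (0.32) lay above 0, IFI44L (-0.55) and OAS1 (-0.37) below. Of the cell cycle genes AURKA stood at 0.30, MCM7 at -0.38, MKI67 at -0.31 and CDK1 at -0.27, and of the proteasome subunits PSMB5 at 0.34, PSMD11 at 0.31, PSMD8 at 0.23 and PSMA3 at 0.26.

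The codes start with C in 3 pairs and H in 5, and the treatment effect was compared between them. CXCL5 changed by 2.25 in the C pairs and 3.08 in the H pairs, ITGA2B by 1.75 and 2.75, TXNRD1 by 0.94 and 0.87, and HLA-DRA by -1.94 and -0.62. In limma's interaction test 0 probe sets passed, the smallest adjusted p was 0.618 and 1753 had an unadjusted p below 0.05. Across all probe sets, which are not independent replicates, the C and H changes had a Pearson correlation of 0.296 and a Spearman correlation of 0.140. Fitted alone, the C pairs gave 0 calls in limma (1999 at an unadjusted p below 0.05) and the H pairs 85, and the interaction test did not show a difference between the letters.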

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

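The tests of the platelet and MHC class II patterns were chosen after the results were seen, and the covariate test of the first principal component was added after the arrays were seen but before its result.

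In 24 of 300 groups of 8 samples (8%), 1 sample lay far from the other 7 by Dixon's test, where chance gives about 1 in 20. In the treated sample of pair 2 the log2 signals of MT1E (9.73), MT1G (9.73), MT1H (10.83), MT1M (6.88) and MT2A (11.83) lay above all other treated samples, whose highest values were 7.95, 7.95, 9.10, 4.54 and 9.89, and its untreated partner was the highest of its group too (9.89, 10.54, 11.15, 7.94 and 11.57). In that sample TIPARP was low at 9.72. BCL2L1 was high in both samples of pair 7, at 9.22 treated and 8.69 untreated, and in its untreated sample the erythroid genes AHSP (8.65) and ALAS2 (9.88) were high too. The treated sample of pair 4 was low in AURKA (4.84) and the mannose receptor MRC1 (5.74, the others from 8.59 to 10.99) and high in CD6 (10.51) and PPP1R15A (9.40). The treated sample of pair 8 was low in CYP1B1 (11.49) and high in OAS1 (7.29). TLR7 was high in the treated sample of pair 6 (5.94) and BAG3 in that of pair 1 (8.88). In the untreated samples, AKR1C1 was high in pair 8 (8.69), CLU low in pair 2 (3.97), FOSB high in pair 3 (6.29), and pair 1 was high in HMGCS1 (7.38) and low in PPP1R15A (6.45). In 18 of these 23 gene signals the partner was the most extreme sample of its own group in the same direction, the exceptions being CD6, CYP1B1, AKR1C1, HMGCS1 and the low PPP1R15A. The array median of the treated sample of pair 5 was high at 5.55.

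The rise of platelet markers may come from more platelet RNA in the treated plates, since 10 of 11 markers had a positive mean change. The marker with a negative change, ITGB3, rose in a dimmer probe set. The count of 10 largely follows from the rise of the list and does not decide. Of 2 transcripts abundant in platelets, PPBP rose by 0.90 and PF4 stood at 0.25 (adjusted p = 0.655). How much of each signal came from platelets was not measured, so more platelet RNA is not excluded, and a change of these genes within cells stays open too. Only the 11 listed markers were weighed here, and a platelet origin of other called rises was not tested.

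The fall of MHC class II genes went beyond that of monocyte markers by -0.71 on average (exact sign-flip p = 0.0234, n = 8 pairs), and the median of 13 monocyte markers was -0.03 (SD 0.64 over markers), with 2 of 13 as low as the class II mean of -0.86. For these 13 markers, and if their expression per cell did not change, this argues against an even loss of monocytes as the whole cause. Other genes of monocytes were not weighed, and expression per cell was not measured. Outside these markers MS4A6A (-1.42), LY86 (-1.24) and CST3 (-1.16), picked from the largest falls, lay below the class II mean, while the myeloid receptor TREM1 rose (1.84). How far these signals came from monocytes was not tested. A part stays open, since the monocyte list passed camera downward in pairs 2, 4, 6 and 7 alone (adjusted p = 0.0191). The monocyte mean was -0.15, and -0.32 without pair 5, where the difference was -0.68 (exact p = 0.0469, and at most that without any other pair). Class II differed from the B cell list by -0.0896 (exact p = 0.703), but pairs went both ways (SD 0.62, from -0.96 in pair 2 to 0.97 in pair 8), so whether fewer B cells may account for it was not settled, although 10 of 10 B cell markers had a negative mean change. Lower expression per cell was not tested and stays open, as does a change in dendritic cells, which carry class II as well.

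The first principal component, which spread mainly the untreated samples, may have shaped the calls. With it as a covariate beside the pair block limma called 735 probe sets, including all 312 called without it. Its scores went both ways within pairs, with the treated sample below its partner in pairs 1, 3 and 8 and above in the others. The covariate could therefore take up little of a treatment effect, and the count does not decide whether the component shaped the calls. Without the 4 pairs that hold an array above 30 on it there were 307 calls, 140 of them among the 312, and without pairs 4 and 6, whose untreated samples lay below -30, there were 10, all among the 312. Leaving out pair 7, whose untreated sample scored -14.3, also left 57, about as few as without pair 6 (45) or pair 4 (70), so the loss was not particular to arrays below -30. The 4 arrays above 30 had the highest SD of signal over probe sets (2.31 to 2.32, next 2.29). The untreated samples of pairs 4, 5 and 6 had the lowest (2.13, 2.16 and 2.18) and scored -48.9, -24.0 and -34.6. The next lowest SD, 2.19 in the treated sample of pair 8, went with a score of 15.3. At its ends the component thus went with the spread of signal. What caused that spread, whether it shaped the calls, and why so many calls need these pairs was not tested and stays open.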

How the results depend on the processing

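The first component as a covariate, the pairs chosen by their scores on it, the lists without PPBP and AKR1C2 and the exact sign-flip test of list means were chosen after seeing the data, and the other alternatives before. No called named gene or list reversed direction in its test, though the median of the immediate early list was -0.0018 in the C pairs alone (adjusted p = 0.837). Over 312 calls (206 higher, 106 lower, 249 at least 1.5-fold), centring, quantile normalization, leaving out dim probe sets, trend and robust settings, a random block and 1 probe set per gene gave 237 to 420.

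Without the pairing as a block, 173 probe sets were called (120 higher, 53 lower, 134 at least 1.5-fold), 139 of them shared, and the metallothionein, NK and red cell lists and 29 named genes no longer passed, while GCLM did (adjusted p = 0.0455); it changed no other call of a named gene or list. With the pairing as a random block the same 3 lists (0.241, 0.0957 and 0.0742) and 9 named genes no longer passed, while APEX1 and GCLM did. With array weights there were 1149 (636 higher, 513 lower, 558 at least 1.5-fold), and with the first component as covariate 735 (394, 341 and 408). The 6 pairs with no array below -30 on that component, which leave out pairs 4 and 6, gave 10 (8, 2 and 10), and 53 named genes and the p53, ATF4, dendritic and NK lists no longer passed. The H pairs alone gave 85 (62, 23 and 85), and the C pairs alone 0 of each (1999 at an unadjusted p below 0.05), with 4 functional and 3 cell marker lists. The exact sign-flip test called 0, 0 higher and 0 lower (3156 at an unadjusted p below 0.05), since its smallest possible p of 0.00781 needs 3472 probe sets to pass and 813 had it (adjusted p = 0.213). An adjusted p below 0.01 left 34 (28 higher, 6 lower), and 2-fold 114. Of 11 functional and 6 marker lists, an estimated correlation left 0 and 0 (3 and 3 unadjusted), fry 3 and 4, and the sign-flip test of list means 0 (7 unadjusted) and 6, adjusted over 22 and 10 lists. Those left by fry were the NRF2, MHC class II and aryl hydrocarbon receptor lists and the B cell, plasma cell, platelet and red cell lists. Apart from the stricter thresholds and the sign-flip test of probe sets, the cause was not tested.

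Leaving out 1 pair at a time gave 45 (without pair 6) to 503 (without pair 1) calls, with 57 without pair 7, 70 without pair 4, 145 without pair 3, 176 without pair 2 and 472 without pair 5. These were 36 to 369 higher, 9 to 221 lower and 45 to 381 at least 1.5-fold, with 10 to 12 functional and 4 to 6 marker lists and 0 interaction calls (0 to 0). All 45 calls without pair 6 and all 57 without pair 7 were among the 312. 12 of the 17 lists that passed did so in all 8 such fits. Signal over background was not analysed here, so how dim signals limit the calls was looked at only by leaving out the probe sets below the median signal (319 calls). Besides the genes given above, dimmer probe sets of PDIA4 (-0.10), HMGCS1 (-0.07), CAT (0.09), MKI67 (0.10) and CD6 (-0.02 and -0.04) moved opposite to the brightest one. None of these passed the test.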

Other observations

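The genes in the next 2 paragraphs were chosen after their values were seen, and so was the count of probe sets with 1 direction, while the tests against other splits of the samples were set before their results.

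These genes were picked from the calls outside the rule for named genes, and no test was made of them as groups. Which cells their signals came from, platelets included, was not measured. The lipoxygenase ALOX12 rose by 1.28 (SE 0.21, adjusted p = 0.0203), neurogranin NRGN by 1.23, the anticoagulant protein S gene PROS1 by 1.21, tissue factor pathway inhibitor TFPI by 1.54, myosin light chain kinase MYLK by 1.16, MYL9 by 1.09, the G protein subunit GNAZ by 1.09 and the histone H2AC6 by 1.09. Among the calls that were lower were CD24 at -0.97, CD37 at -0.85, BCL11A at -0.84, HLA-DOB at -0.67 and CD200 at -0.87 (adjusted p from 0.0267 to 0.0437). The integrin subunit ITGB3, a platelet marker, stood at -0.24 in its brightest probe set and rose by 1.92 in a dimmer one.

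Fibronectin FN1 fell by 2.48 (SE 0.53, adjusted p = 0.0462) and the chemokine receptor CCR2 by 1.99 (SE 0.35, adjusted p = 0.0261), each lower in 7 of 8 pairs, and complement C3 stood at -1.59 and CPVL at -1.56. The IgA receptor FCAR rose by 1.41, vanin VNN1 by 1.43 and NAMPT by 1.29. BACH1, the repressor that competes with NRF2, rose by 1.06 (SE 0.18, adjusted p = 0.0207), and the aldo-keto reductase AKR1C3 by 0.91. 813 of 22215 probe sets (3.66%) moved 1 way in all 8 pairs, where chance gives 0.781% on average if probe sets have no effect. Probe sets are not independent, so the share can vary by chance, and it was not set against the label swaps.

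The labels were swapped within pairs in 100 of the 128 ways to do so, the real one included. The mirror of a split exchanges higher and lower, so the larger of its counts was taken for either direction (as drawn, the other splits gave at most 6 higher and 51 lower). As many calls came from 1 of 100 for all 312 (highest other 56), 1 for 206 higher (51), 1 for 106 lower (51) and 1 for 249 at least 1.5-fold (48), and 96 other splits had 0 calls. Chance is therefore unlikely for these counts but not excluded, since 1 of 100 is the smallest share these splits can give. For the number of lists past camera other splits did as well more often. At least 11 functional lists shifted in 11 of 100 splits (highest other 14), and at least 6 marker lists in 18 (highest other 9). The other splits with at least 6 marker lists swapped 1 to 3 pairs, so most pairs kept the real direction. Those with at least 11 functional lists swapped 1 to 7 pairs, where swapping 7 mirrors swapping 1. Part of a treatment effect can remain in such splits, so these shares do not measure chance alone. Even so, a split that swapped 4 of 8 pairs, which keeps no direction, shifted 11 functional lists. Nearly all other splits shifted some functional lists, and most shifted some marker lists. A list past camera at the preset correlation therefore cannot by itself be taken as an effect of the treatment. The interaction with the code letter called 0. Any split gives at least 0, so the count of 56 of 56 splits of the pairs into 3 and 5 was fixed beforehand and decides nothing (highest other 48).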
